A study of Mus musculus with 1249 samples.

How the data were processed

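Transcripts of mouse intestinal organoids were counted by targeted RNA sequencing, in which amplicons of a fixed panel are amplified from each well and sequenced. The table has 206 entries, of which 4 are genomic DNA controls; these hold 0.085% of all counts and were left out of library sizes and tests, leaving 202 genes. The deposited values of 1159 of the 1249 libraries are raw counts per amplicon, made by the authors with tools that the submitters' processing notes name as bcl2fastq, UMI-tools 0.5.3, Bowtie 1.2.2, SAMtools 1.2.7 and Cufflinks 2.2.1 with the mm10 build, in roles that are not given. The 90 libraries of Plate 60 are deposited as a score: the authors' values were scaled to a total of about 65000 per library, so this plate was left out of the tests. For 88 of these libraries whole reads could be recovered (99.96% of values above 0 came out whole within 0.5 of a deposited unit), and they were used as an added alternative. A sample sheet, per the labels, holds an other, text kind of value, the name of the experiment set, which was not a term of any test. The WT plates named Set_2 there are those of plate set E, which was also compared with AKP by itself. Values of Defa24 and Defa6 are the same in every library and are 1 measurement, counted as 2 genes.

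Groups were taken from the labels: genotype, treatment, plate and days. The titles and characteristics of 42 samples give different days, and the title was used; 23 samples titled 1 day were left out of the main comparisons. The WT plates form 5 plate sets, A to E. Sets A to D each join plates that hold the same drugs. Set E joins the other 4 WT plates, which do not all hold the same drugs. Replicate numbers of the titles do not pair samples: the median correlation across genes of the departures of reference libraries from their group mean was 0.456 for libraries of the same plate and number, 0.455 for the same plate and another number, and -0.02 for different plates and numbers, so plate was the model term. No library was a copy of another, and all 4260 pairs of replicates differed by more than sampling noise in a chi-square test.

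Counts were tested with edgeR 4.0.16 under R 4.3.3 by the quasi-likelihood F test with robust estimates, TMM scaling and filterByExpr (minimum count 10, minimum total 15), with plate as a term. Benjamini-Hochberg adjustment ran over the genes of a comparison, or over all drug-gene pairs of the screen, and calls were made at an adjusted p of 0.05. AKP and WT Control wells were compared on counts summed per plate, because no plate held both genotypes. Each drug of the WT screen was tested against the Control wells of its plates, 1 fit per plate set. The difference between genotypes was the interaction of drug and genotype, and analogs were compared by the difference of their fold changes. DESeq2 1.42.0 (Wald test) was the other tool, and Rcpp 1.1.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 served the computing and drawing.

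Before the data were examined, 28 gene lists, 22 drug classes, 20 analog pairs, the tests, the alternatives and the rule for named genes were fixed. The 15 lists with at least 3 measured genes were tested: enterocyte, goblet, Paneth, enteroendocrine, tuft, stem cell, WNT target, proliferation, Notch, EGFR and MAPK, BMP and TGF-beta, NF-kB, p53 target, glycolysis and hypoxia, and housekeeping. The only measured genes of the glycolysis and hypoxia list, called glycolysis genes below for short, are Vegfa, Pdk1 and Hif1a, so glycolysis itself was not measured. Lists were tested with fry of limma 3.58.1, whose p tests whether the genes of a list move, on balance, one way; it does not compare the list with other genes. Classes were compared by a two-sided permutation test of the mean list score of the class against random sets of other drugs, with 100000 resamples and Benjamini-Hochberg adjustment over the 315 class-list pairs. Drugs of a set share their Control wells, so their calls are not independent. The class test treats drugs as independent units, so its p can be too small for a class whose drugs share Control wells.

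Genes are named by this rule: those past the threshold with the largest absolute change, up to 12 higher and 12 lower for each reference condition and for AKP against WT and up to 5 each way for a drug, and in each list the 2 to 4 members with the largest change past the threshold. Drugs described are the 15 with the most genes and members of the fixed classes and pairs, and genes across the screen are the 10 changed by most drugs. A gene at 3 counts or fewer in every library of a comparison is not named. Names outside the rule are marked as chosen after their values were seen.

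The most abundant gene took 8.75% of counts and the 10 most abundant 40.41%. The reads come from PCR, and the sources used here do not state that they were collapsed to molecules, so intervals and floors cover counting error only. A group without counts was set at a floor of 3 counts over the group, which gives a bound, and a group with 1 to 3 counts is given as a ratio with a 95% counting interval. The tests were tested on simulated data made from these counts: 4-fold changes were recovered for 100% of genes in the reference conditions, 95.7% in the screen, 95% for AKP against WT, 80.9% for drugs in AKP, 47.7% for the difference between genotypes and 100% for an analog pair. For 2-fold changes these shares were 45% to 85%, 45.8%, 20%, 40.7%, 9% and 80%. Of unchanged genes between 0.253% and 7.21% were called, most for Stem_cells. Simulated changes went up and down in equal numbers and were 4-fold at most. Recovery where most changes go one way and are larger, as in AKP against WT, was not simulated.

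The alternatives were DESeq2 size factors in edgeR, total counts, scaling by the housekeeping genes, DESeq2, no filter on low counts, no plate term, the replicate number in place of plate, other sets of libraries (without libraries under 10% of their plate median, plate sets A to D only, libraries titled 1 day), other drug wells in place of Control wells, and leaving out single libraries or plates. Coordinates come from the GRCm38 annotation. Treatments with a single library are not tested. Doses, vehicle and well positions are not in the labels.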

Results

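The data are counts of a targeted panel of transcripts in mouse intestinal organoids, cultures of gut epithelium that hold stem cells and their differentiated offspring. Wild-type (WT) organoids and tumour organoids with mutations in Apc, Kras and Trp53 (AKP) were grown in wells of 26 plates and exposed to a library of drugs, mostly for 2 days. There were 1144 WT and 105 AKP samples. The WT wells held 320 drug labels with at least 2 libraries per treatment, 72 Control libraries and 4 reference conditions: Stem_cells (9 libraries), Enterocytes (17), EECs (10) and IFNg (10). The AKP wells titled 2 days held 29 Control libraries and 15 drugs with at least 2 libraries. Drug doses are not in the labels.

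Total counts ran from 1173 to 169213 per library (median 38051) over the 1159 libraries deposited as counts. WT Control libraries held 3811 to 124880 counts, Stem_cells 3669 to 56913, Enterocytes 10637 to 62450, EECs 3502 to 48234 and IFNg 5875 to 55938. AKP libraries held 2295 to 168021 counts. Of the 202 genes of the panel, Lrig1 had no count in any library. Changes below are log2 fold changes ± standard error from edgeR, with n the number of libraries. Replicates are not stated to be separate cultures, so the p-values measure the spread between these samples.

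The first comparison asked how wells labelled Stem_cells differed from Control wells (n = 9 on 7 plates against 72). Several goblet and enteroendocrine transcripts fell. Agr2, a protein disulfide isomerase needed for mucin folding, fell in 7 of 7 plates (-1.65 ± 0.19), as did the mucin Muc2 (-1.46 ± 0.20) and the peptide hormone Cck (-1.52 ± 0.32). Hck, a kinase of tuft cells (-2.87 ± 0.55), and the chemokine Ccl6 (-2.74 ± 0.37) fell furthest. Vim, an intermediate filament protein (2.52 ± 0.29), the interferon-induced chemokine Cxcl9 (2.67 ± 0.61) and the fatty acid binding protein Fabp1 (2.49 ± 0.29) rose most. They were higher than Control in 6, 5 and 6 of 7 plates.

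By list, 5 of the 8 goblet cell genes fell in Stem_cells and 3 did not pass (6 adjusted over the list alone), among them Muc2, Agr2 and Zg16, a granule lectin (-1.36 ± 0.28). Of 10 enteroendocrine genes, 5 fell, among them Chgb, a granin of secretory granules (-1.96 ± 0.22), and Tac1, the tachykinin precursor (-2.09 ± 0.58), while Vim rose and 4 did not pass (7 adjusted over the list alone). Of 13 Paneth cell genes 3 fell, the phospholipase Pla2g2a rose (1.28 ± 0.36) and 9 did not pass. Of 5 tuft cell genes 2 fell, among them Hck, while the phospholipase Plcg2 rose (0.88 ± 0.22, 4 of 7 plates) and 2 did not pass. Of 10 enterocyte genes 2 rose, Fabp1 and Fabp2, another fatty acid binding protein (1.96 ± 0.56), and 8 did not pass. Of 18 stem cell genes 2 rose, the receptor Tnfrsf19 (1.36 ± 0.29) and the hyaluronan receptor Cd44 (0.57 ± 0.18), and 16 did not pass. Tnfrsf19 and Cd44 were each higher than Control in only 4 of 7 plates. Lgr5, the R-spondin receptor of crypt base stem cells, named here after its values were seen, was -0.15 ± 0.21 and did not pass. Both genes that rose among the 10 WNT target genes were these stem cell genes. The 7 proliferation genes, the 6 NF-kB genes and the 5 EGFR and MAPK genes did not pass; the EGFR list had a mean of 0.03 and a median of -0.03. The p53 target list, in which Bax, a pro-apoptotic BCL2 relative, rose (0.55 ± 0.15), had a mean of -0.11, a median of -0.29 and a set test pointing up. In all 37 of 175 genes changed, 20 higher and 17 lower, 20 of them at least 2-fold. The call of Cd44 was lost without replicate 1 on Plate 9 or replicate 5 on Plate 8, that of Fabp2 without replicate 7 on Plate 6 rep, and that of Pla2g2a without replicate 1 on Plate 11.

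The Enterocytes wells (n = 17 on 9 plates) were compared with the same Control wells. All 10 enterocyte genes rose, led by Fabp1 (4.27 ± 0.21, 9 of 9 plates), Fabp2 (2.68 ± 0.37), the glutathione transferase Gstm3 (2.54 ± 0.22) and Reg1, a secreted lectin (2.45 ± 0.30), with Alpi, the intestinal alkaline phosphatase, at 2.23 ± 0.15. Stem cell genes fell, 16 of 18, with Olfm4, a glycoprotein of crypt stem cells, at -4.12 ± 0.29, Lgr5 at -3.77 ± 0.21 and Ascl2, a WNT-driven transcription factor of stem cells, at -3.65 ± 0.35. All 10 WNT target genes fell, with Axin2, a feedback inhibitor of the pathway, at -2.48 ± 0.17, and so did all 7 proliferation genes, with the cyclin Ccnb1 at -2.35 ± 0.20 and the proliferation marker Mki67 at -1.98 ± 0.17.

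Other secretory lists moved apart in Enterocytes. Goblet genes rose, 5 of 8, with Zg16 at 1.79 ± 0.16 and Muc2 at 1.46 ± 0.12. Paneth genes fell, 8 of 13, with 1 higher and 4 not past, among them Habp2, a secreted protease (-1.40 ± 0.25). Notch genes gave 4 lower and 1 higher of 6, EGFR and MAPK genes 4 lower of 5 with Etv4, an ETS factor downstream of MAPK, at -3.15 ± 0.26, and BMP genes 3 higher and 1 lower of 4. All 3 genes of the glycolysis and hypoxia list rose (Vegfa, Pdk1 and Hif1a). Enteroendocrine genes gave 3 higher, 1 lower and 6 not past. NF-kB (1 higher, 2 lower), tuft (1 and 1), p53 (1 and 1) and housekeeping genes (1 lower of 3) had list means whose sign turned under at least 1 other scaling. In all 122 of 175 genes changed, 58 higher and 64 lower, 54 of them at least 2-fold. Scaling by DESeq2 size factors moved the median of all genes by 0.20 and gave 79 higher and 50 lower, housekeeping scaling moved it by 0.37 and gave 87 and 40, and total counts by -0.13 and gave 45 and 74.

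EECs wells (n = 10 on 6 plates), named for enteroendocrine cells, differed from Control in that 9 of 10 enteroendocrine genes rose (adjusted set test p = 1.1e-24). Chga, a granin (3.06 ± 0.37), and the hormones Gip (3.17 ± 0.25) and Cck (2.58 ± 0.20) led. Enterocyte genes rose as well, 8 of 10, with Anpep, a brush border aminopeptidase, at 3.10 ± 0.20 and Reg1 at 3.27 ± 0.35. Stem cell genes fell, 14 of 18, with the water channel Aqp4 at -2.10 ± 0.23 and Lgr5 at -1.78 ± 0.27. Tuft cell genes rose, 4 of 5, with the cation channel Trpm5 at 1.63 ± 0.28, as did 5 of 8 goblet and 5 of 13 genes of the Paneth list. Among the latter was the peptide Guca2b at 2.02 ± 0.17, whose rise alone does not show a gain of Paneth cells.

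WNT target genes fell in EECs, 7 of 10, with Axin2 at -1.38 ± 0.20, proliferation genes fell, 6 of 7, with the thymidine kinase Tk1 at -1.71 ± 0.23, and all 3 p53 target genes fell, with Bax at -0.94 ± 0.18. Notch genes gave 3 lower of 6 and EGFR genes 3 lower of 5, with Etv4 at -2.90 ± 0.42. BMP (1 higher, 2 lower), glycolysis (1 and 1) and NF-kB genes (1 and 1) turned the sign of their mean under at least 1 other scaling. Cxcl9 rose (4.42 ± 0.38), as did Stat1, the transcription factor of interferon signalling (2.43 ± 0.22). Cxcl9 was 3.25 ± 0.44 without replicate 1 on Plate 15, and Stat1 was lowest, at 1.66, without replicate 1 on Plate 16. In all 104 of 175 genes changed, 46 higher and 58 lower. DESeq2 size factors moved the median of all genes by 0.42 and gave 69 higher and 32 lower, housekeeping scaling by 0.25 and gave 56 and 37, and total counts by -0.22 and gave 38 and 75.

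IFNg wells (n = 10 on 5 plates), named for interferon gamma, showed the largest single change of these conditions in Cxcl9 (8.99 ± 0.26), with Stat1 at 4.69 ± 0.17. All 6 NF-kB genes rose, with the cytokine Tnf at 5.44 ± 0.28, the inhibitor Nfkbia at 1.70 ± 0.16 and the ubiquitin ligase Birc3 at 1.57 ± 0.16 (adjusted set test p = 4.4e-33). Proliferation genes gave 6 higher and 1 lower of 7, with the cyclins Ccnd1 at 1.45 ± 0.16 and Ccne1 at 1.44 ± 0.20. Paneth genes fell, 9 of 13 with 2 higher, among them the colipase Clps (-3.09 ± 0.34) and the defensin Defa24 (-2.72 ± 0.36), whose deposited values are the same as those of Defa6, so that both are 1 measurement, counted as 2 genes in every Paneth tally and gene total here. Stem cell genes fell, 12 of 18 with 2 higher, with Olfm4 at -2.94 ± 0.36 and Lgr5 at -2.73 ± 0.26.

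Tuft genes fell in IFNg wells, 4 of 5, with Pou2f3, the tuft cell lineage factor, at -2.71 ± 0.25. Goblet genes fell, 6 of 8 with 1 higher, with the secreted Spink4 at -2.48 ± 0.16. Enterocyte genes gave 5 lower and 1 higher of 10, with Reg1 at -4.86 ± 0.94 and the apolipoprotein Apoa4 at -2.97 ± 0.28. WNT targets gave 5 lower and 2 higher of 10, Notch genes 4 lower and 1 higher of 6, and BMP genes 2 lower and 1 higher of 4. EGFR genes gave 3 higher and 1 lower of 5, with the ligand Areg at 3.24 ± 0.20, and 2 of 3 glycolysis genes rose, with the hypoxia factor Hif1a at 2.93 ± 0.17. Enteroendocrine genes split, 5 higher and 4 lower of 10, and the 3 p53 and 3 housekeeping genes did not pass. The means of the enteroendocrine, p53 and housekeeping lists turned sign under total counts. In all 131 of 175 genes changed, 64 higher and 67 lower, 75 of them at least 2-fold, and DESeq2 size factors moved the median by 0.27 and gave 81 higher and 51 lower, and total counts by -0.12 and gave 57 and 74.

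**Figure D1:**
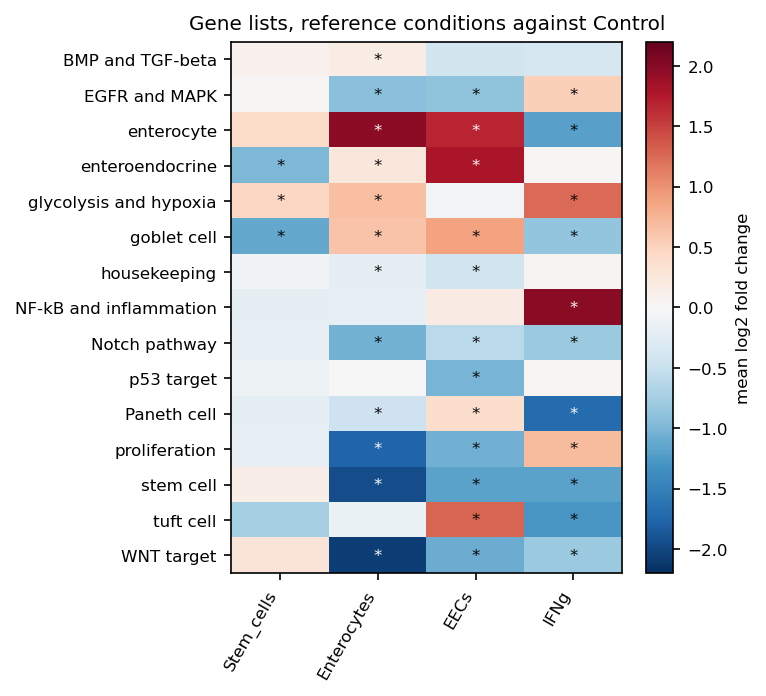
Mean log2 fold change of each gene list (vertical axis) in each reference condition against Control. Stars mark lists whose adjusted fry p is under 0.05, and the enterocyte list had a mean of 1.96 in Enterocytes.

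The screen asked which drugs shift the cell types of WT organoids. Defensin transcripts were those most often changed: Defa24 passed in 80 treatments, lower in 79. Ccl6 passed in 66, lower in 59. Areg rose in 50 of its 51 calls, and Chga (42 calls) and Anpep (36 calls) were higher in each. The other genes among the 10 most often changed were the matrix protein Prelp (48 calls, 37 lower), Ay761184, a defensin (40), the lysozyme Lyz1 (39), Clps (37, of which 36 lower) and Defa17 (37). Of these genes 4 also differed between all drug wells and the Control wells by more than 95% of permutations, on average over 13 plates by -0.84 for Defa24, 0.71 for Chga, -0.53 for Ccl6 and -0.53 for Defa17. For Areg this difference was 0.45, and 129 of 1000 permutations gave a shift of any gene as large. Drugs of a set share their Control wells, and screens with permuted labels gave 1 gene in up to 22 drugs of a set. Ret_acid, a label taken as given, changed most genes, 88 (n = 4). Its libraries sit on 1 plate, with 3 Control libraries, so no other plate repeats these calls. With Ret_acid Cxcl9 rose (5.72 ± 0.66), Bhlhe40, a circadian and stress repressor, rose (2.07 ± 0.22) and Clps fell (-4.12 ± 0.41). Id1, a BMP target, had no count with Ret_acid and was at least 13.3-fold lower than Control at a floor of 3 counts over the group, and the cell cycle inhibitor Cdkn1a had 2 counts, a ratio to Control of 0.0106 (95% counting interval 0.00128 to 0.0387).

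Enteroendocrine transcripts rose with statins, inhibitors of cholesterol synthesis. Their mean enteroendocrine score, the mean log2 fold change of the list, exceeded that of the other drugs by 1.74 (two-sided permutation p = 1e-05, the smallest the permutations can give), with Lovastatin at 1.69, Simvastatin at 1.48, Atorvastatin at 2.00 and Fluvastatin at 2.02. Simvastatin and Fluvastatin shared the Control wells of Plate 73 74, which the permutations do not take into account, so this p may be too small. Cck rose with Atorvastatin (3.03 ± 0.29, n = 3), Fluvastatin (3.40 ± 0.47, n = 2), Simvastatin (2.58 ± 0.46, n = 2) and Lovastatin (2.39 ± 0.29, n = 2). Chga rose with Atorvastatin (3.90 ± 0.43) and Chgb with Fluvastatin (2.62 ± 0.35). NF-kB genes rose with statins too, by 1.17 over the other drugs, with Nfkb2, an NF-kB subunit, at 2.01 ± 0.24 with Lovastatin and 1.73 ± 0.27 with Simvastatin, and Tnf at 3.53 ± 0.54 with Atorvastatin. Atorvastatin changed 77 genes, with Nupr1, a stress protein, higher (2.33 ± 0.19) and the stem cell genes Aqp4 (-2.27 ± 0.27) and Cdca7 (-1.85 ± 0.30) lower. The statin class also passed for Paneth (0.83), tuft (0.75) and EGFR genes (0.46) and for BMP genes (-0.68).

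Anthracyclines and topoisomerase inhibitors, which damage DNA, exceeded the other drugs in enterocyte score by 1.62 (permutation p = 1e-05), from 0.97 with Epirubicin to 2.06 with Doxorubicin (4 of 4 drugs above 0). Anpep rose with Epirubicin (4.41 ± 0.43, n = 2), Daunorubicin (3.86 ± 0.45, n = 2) and Irinotecan (2.80 ± 0.38, n = 3). Proliferation (-1.31), tuft (-1.19), stem cell (-1.07) and Notch genes (-0.75) were lower in this class and goblet genes higher (0.57). Olfm4 fell with Doxorubicin (-4.46 ± 0.98) and Epirubicin (-3.96 ± 0.66), Cdkn1a rose with Daunorubicin (2.72 ± 0.55), and Aqp4 fell with it (-3.18 ± 0.47). Zg16 rose with Doxorubicin (2.71 ± 0.41, and 1.26 without Plate 11). Ccnb1 had no count with Epirubicin, at least 4.90-fold lower than Control.

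Antimetabolites had higher scores than the other drugs for enteroendocrine (0.83, above 0 in 6 of 6 drugs, led by Gemcitabine at 1.51), enterocyte (0.79), Paneth (0.78) and goblet genes (0.47) and lower scores for glycolysis genes (-0.41). Gemcitabine raised Anpep most of the drugs described (5.50 ± 0.39, n = 2), with Guca2b at 3.37 ± 0.27. Azaguanine (n = 4) raised Ay761184 (1.79 ± 0.21) and Cpe, a prohormone carboxypeptidase (1.72 ± 0.29), and lowered Fgfbp1, an FGF carrier (-1.53 ± 0.19). Phenothiazines exceeded the other drugs in NF-kB score by 0.45 (adjusted permutation p = 0.0187), from 1.27 with Fluphenazine to -0.44 with Prochlorperazine. Fluphenazine shared the Control wells of Plate 73 74 with Simvastatin and Fluvastatin. The NF-kB results of phenothiazines and statins are therefore not independent. Nfkb2 (1.42 ± 0.27) and Nfkbia (1.44 ± 0.32) rose with Fluphenazine. Perphenazine (n = 3) raised Tnf (3.35 ± 0.55) and Areg (2.26 ± 0.28) and lowered Apoa4 (-1.82 ± 0.35). Glucocorticoids and mineralocorticoids had lower tuft scores than other drugs (-0.57, 7 of 7 drugs below 0). Tubulin ligands other than the benzimidazoles had lower WNT (-0.98) and stem cell scores (-0.86), a difference carried by Colchicine (-2.98 and -2.63). Retinoids had lower BMP (-0.66), Notch (-0.52) and p53 scores (-0.99), the last carried by Ret_acid (-3.26).

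**Figure D2:**
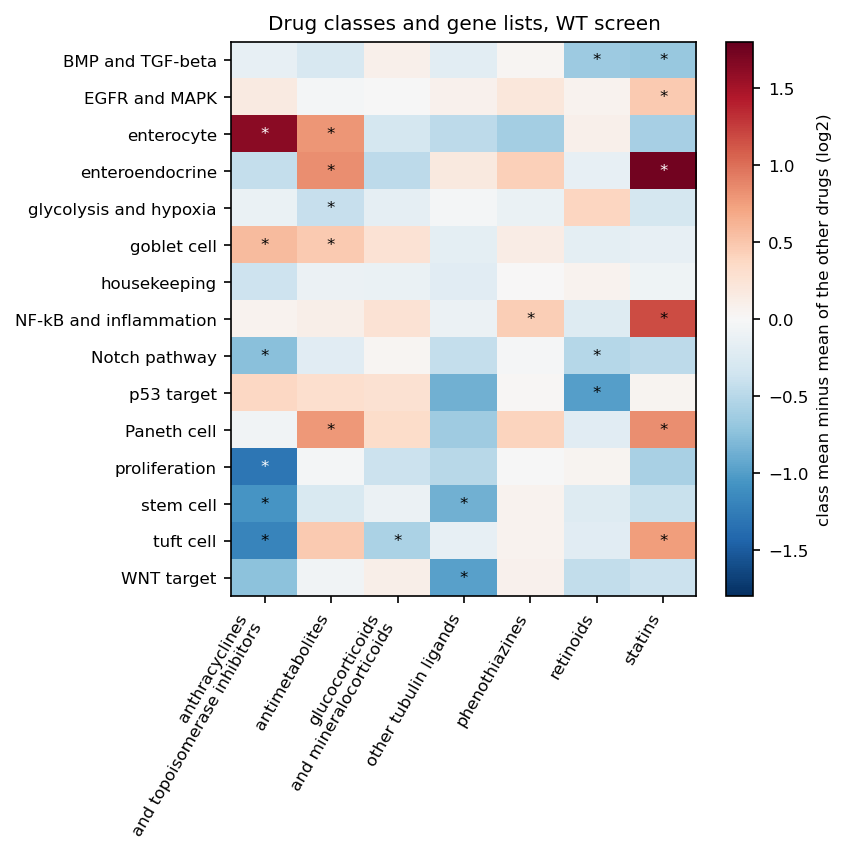
Difference in list score (log2) between the drugs of each class and the other drugs of the WT screen. Stars mark adjusted permutation p under 0.05, among them enteroendocrine genes in statins (1.74).

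Further single drugs follow, some of them members of the fixed classes, such as the tubulin ligands Colchicine and Griseofulvin. The anthelmintic Pyrvinium (51 genes, n = 4) raised Areg (3.15 ± 0.24), Anpep (3.04 ± 0.29) and Nupr1 (2.39 ± 0.17) and lowered Clca4 (-2.55 ± 0.50) and Lgr5 (-1.98 ± 0.35). Clca4 is a synonym of a pair of mouse genes, Clca3b and Clca4a, and the panel does not say which. Erlotinib, an EGFR inhibitor (n = 3), raised Anpep (4.21 ± 0.31) and lowered Tk1 (-2.06 ± 0.28) and Ccnb1 (-2.04 ± 0.29). Colchicine (n = 2) raised Reg1 (3.59 ± 0.60), Anpep (3.32 ± 0.49) and Guca2b (3.21 ± 0.35). Olfm4 fell with Minoxidil (-3.38 ± 0.50, n = 3), Thalidomide (-3.02 ± 0.47, n = 3) and Griseofulvin (-2.72 ± 0.46, n = 3). Minoxidil raised Anpep (2.93 ± 0.39), Thalidomide raised Areg (2.64 ± 0.36) and Griseofulvin lowered Clca4 (-2.61 ± 0.46).

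Over the 320 drug labels, 70 changed at least 10 genes and 45 changed none in edgeR. Of 59320 treatment-gene pairs 2400 passed (8476 at unadjusted p under 0.05), 1220 higher and 1180 lower, 1768 of them at least 2-fold. Of 4815 treatment-list pairs 292 passed the set test: Paneth genes most often (12 up, 55 down, with Defa24 and Defa17 of the shift above in the list), then NF-kB (26 up), stem cell (9 up, 15 down), enteroendocrine (22 up, 1 down), proliferation (1 up, 22 down), goblet (13 and 7), enterocyte (17 and 2), glycolysis (7 and 10), WNT (9 and 6), Notch (5 and 8), housekeeping (2 and 10, all of which turned sign under housekeeping scaling), EGFR (11 up), tuft (6 and 5), BMP (1 and 6) and p53 genes (3 and 1). Housekeeping scaling uses the genes of the housekeeping list itself, so the turn of that list follows from the scaling. Other lists also hold genes that differed between all drug wells and Control wells. These were Chga (0.71) in the enteroendocrine, Ccl6 (-0.53) in the goblet and Ascl2 (0.59) in the stem cell and WNT lists. Of 315 class-list pairs 24 passed, and none of these turned sign under another scaling. Against all other drug wells of the same plates in place of the Control wells, 24 drugs reached 10 genes and 827 pairs passed, and 45 of the 51 drug-gene values named above passed there too. The 6 named values of Simvastatin, Fluvastatin and Fluphenazine did not pass there, but these drugs are the only ones of Plate 73 74 (14 libraries, 8 of them Control) and were set against each other, so for them the comparison does not test the Control wells. The split of the 2400 pairs followed the scaling (DESeq2 size factors 1646 and 911, housekeeping genes 1567 and 618), with a median shift of 0.10 under housekeeping scaling, and without Plate 8 the number of drugs was 48.

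AKP organoids were compared with WT organoids in Control wells, with plates as replicates (7 AKP and 16 WT plates). Trp53 (chromosome 11, 69580348 to 69591873, GRCm38), which the labels give as mutated, had no count in AKP Control wells against 905 in WT, at least 254-fold lower at a floor of 3 counts over the group. Kras (chromosome 6, 145216699 to 145250420) rose (1.72 ± 0.17). Apc is not on the panel. Part of the transcripts of differentiated cells had 3 counts or fewer in AKP Control wells. Genes with no count and genes with 1 to 3 counts were 1 and 3 of 10 enterocyte and 4 and 3 of 12 enteroendocrine genes. They were 3 and 2 of 9 goblet, 2 and 1 of 13 Paneth and 1 and 1 of 6 tuft genes. Zg16 and Tff3, a trefoil peptide, had no count and were at least 1690-fold and 506-fold lower, as was the hormone Gip at least 367-fold. Among genes with counts in AKP, the brush border disaccharidase Sis was at -13.11 ± 0.70, Ay761184 at -13.10 ± 1.02, Defa17 at -12.93 ± 0.91 and Olfm4 (chromosome 14, 80000302 to 80023141) at -11.57 ± 0.59.

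All 10 enterocyte genes were lower in AKP, with Apoa4 at -11.16 ± 0.77, as were 11 of 12 enteroendocrine genes, 8 of 9 goblet genes, 11 of 13 Paneth genes, with Lyz1 at -10.56 ± 1.16, and 5 of 6 tuft genes. The exception among enteroendocrine genes was Cpe, which rose (3.38 ± 0.33). All 3 p53 genes fell: Trp53, Cdkn1a (-1.92 ± 0.64) and Bax (-1.42 ± 0.32). Proliferation genes rose, 6 of 9, with the phosphatase Cdc25c at 1.64 ± 0.42 and Ccnb1 at 1.17 ± 0.16. EGFR and MAPK genes rose, 3 of 5, with Etv4 at 1.55 ± 0.30 and the receptor Egfr at 1.16 ± 0.20. Stem cell genes split, 5 higher and 8 lower of 19 (13 adjusted over the list alone), with Tnfrsf19 (3.18 ± 0.40) and Cd44 (2.62 ± 0.22) higher. Lgr5 (chromosome 10, 115450314 to 115587780), named after its values were seen, was -0.09 ± 0.41 and did not pass. WNT targets gave 4 higher and 2 lower of 11, Notch genes 2 higher and 4 lower of 7, NF-kB genes 2 and 2 of 5, BMP genes 1 and 1 of 4 with Bambi, a pseudoreceptor of the pathway, higher (2.51 ± 0.23), and glycolysis and housekeeping genes 1 higher of 3 each. The BMP list had a mean of 0.19, a median of -0.02 and a set test pointing up, and the housekeeping list a mean of -0.10 with a test pointing up. Further genes that rose were Hoxa5, a homeobox factor (3.33 ± 0.40), Klf4, a differentiation factor (3.36 ± 0.64), and Nupr1 (2.35 ± 0.32).

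In all 135 of 185 genes differed, 49 higher and 86 lower in AKP, 112 of them at least 2-fold. Within plate set E, which holds 4 WT plates, 120 genes passed, 46 higher and 74 lower, and 100 passed in both in the same direction. The lists there gave, higher and lower, 0 and 9 enterocyte genes, 1 and 8 enteroendocrine, 0 and 5 goblet, 2 and 10 Paneth, 0 and 4 tuft, 0 and 1 p53, 6 and 0 proliferation, 4 and 0 EGFR, 7 and 6 stem cell and 7 and 1 WNT target genes. There Kras was 1.33 ± 0.15, Tnfrsf19 3.59 and Cd44 2.48, while Klf4 (2.12), Cdkn1a (-1.62) and Bax (-0.67) did not pass and Lgr5 was 1.07 and did not pass. For 67 genes the values of the AKP plates and of the WT plates did not overlap, so the spread among plates of a genotype does not account for these. Each plate held 1 genotype, and a difference other than genotype that all AKP plates share was not tested. All AKP plates belong to the experiment named Set_2, as do the WT plates of set E, while the other WT plates belong to other experiments. Only the comparison within set E therefore holds the experiment constant. DESeq2 size factors moved the median of all genes by -0.26 and gave 38 higher and 95 lower, total counts by 0.31 and gave 55 and 80, and housekeeping scaling by -0.16. The BMP list mean turned sign under DESeq2 size factors, those of NF-kB and housekeeping genes under total counts.

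**Figure D3:**
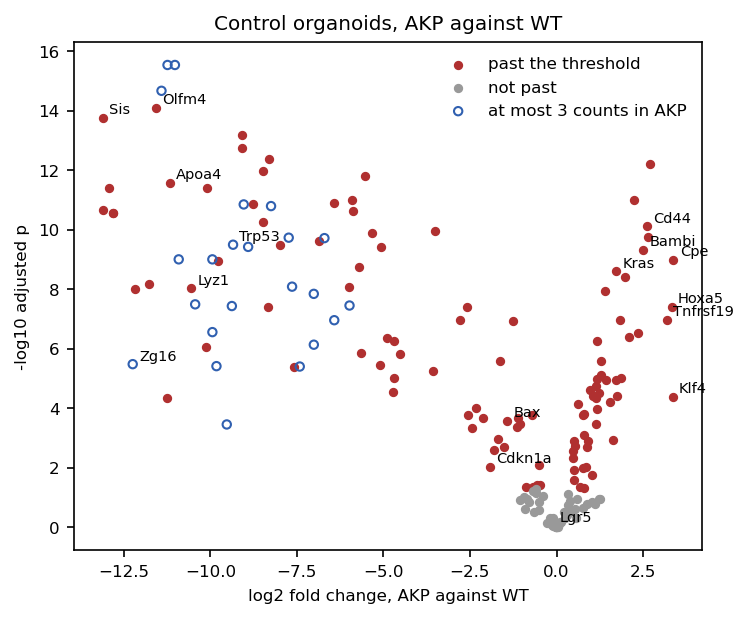
Log2 fold change of each gene in AKP against WT Control wells (horizontal axis) against the -log10 adjusted p of edgeR (vertical axis). Red points passed, and hollow points are genes with at most 3 counts in AKP, whose fitted values are not bounds; Sis lies at -13.11 and Cpe at 3.38.

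Drugs were then compared with Control in AKP wells (15 drugs, 149 genes). Ephb2, an ephrin receptor driven by WNT, and Pdia6, a protein disulfide isomerase, fell with all 15 drugs, Ephb2 by between -0.35 and -2.16. Lgr5 fell with 13, Ctnnb1, which encodes beta-catenin, rose with 14, and Nfkb2 rose with 11. In 100 permuted sets no gene passed in more than 4 drugs. These permutations test chance only. Drugs share the Control wells of their plates, and a difference between the Control wells and all drug wells was not tested in AKP. WNT target lists fell with 10 drugs and NF-kB lists rose with 8, most with Trifluoperazine (1.63), Atorvastatin (1.54) and Lovastatin (1.47). Tnf rose with Atorvastatin (2.98 ± 0.42, n = 3) and Lovastatin (3.05 ± 0.46, n = 3), while Lgr5 fell (-1.99 ± 0.26 and -2.32 ± 0.30). All AKP libraries of both statins sat on the plate titled extra and shared its 3 Control wells, so their values are not independent. Vim and Clca4 rose with Minoxidil (6.18 ± 0.38 and 6.08 ± 0.43, n = 2) and Floxuridine (5.71 ± 0.35 and 5.27 ± 0.39, n = 2).

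Further values in AKP followed the drug. Atorvastatin raised Nfkb2 (1.62 ± 0.14) and Egfr (1.90 ± 0.19), and Lovastatin raised Nfkbia (1.60 ± 0.34) and lowered Agr2 (-2.21 ± 0.25). Colchicine (n = 2) raised Clca4 (4.35 ± 0.48) and lowered Agr2 (-3.33 ± 0.30), and raised Vim (2.45 ± 0.56), a call lost without replicate 2 on Plate 99, which leaves 1 library, assumed to vary like the other groups. The benzimidazoles Albendazole (-2.43 ± 0.42) and Mebendazole (-2.65 ± 0.43) lowered Nupr1 (n = 2 each), and Trifluoperazine raised it (2.12 ± 0.32) and lowered the stearoyl-CoA desaturase Scd2 (-2.73 ± 0.31) and Tnfrsf19 (-3.25 ± 0.38, 9 counts in the drug wells). Lgr5 also fell with Minoxidil (-2.82 ± 0.46), Tamoxifen (-2.73 ± 0.46), Floxuridine (-2.67 ± 0.35) and Opipramol (-0.97 ± 0.17, n = 6). By list, the glycolysis and hypoxia genes (Vegfa, Pdk1 and Hif1a) fell with 11 drugs (with Lovastatin the mean was -0.64 and the median 0.14). Goblet genes fell with 9, proliferation genes with 8 and BMP genes with 7. Albendazole (0.54) and Colchicine (0.45) raised proliferation genes and Floxuridine raised BMP genes (0.99). The tuft list test pointed up with 14 drugs although its mean was negative in 5. Of 2235 drug-gene pairs 726 passed, 321 higher and 405 lower, and of 210 drug-list pairs 96 passed. Genes per drug ran from 18 (Irinotecan, 8 without its replicate 1 on Plate 96, which again leaves 1 library) to 67 (Atorvastatin), and without Plate 96, which left fewer drugs with 2 libraries, 382 pairs passed.

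**Figure D4:**
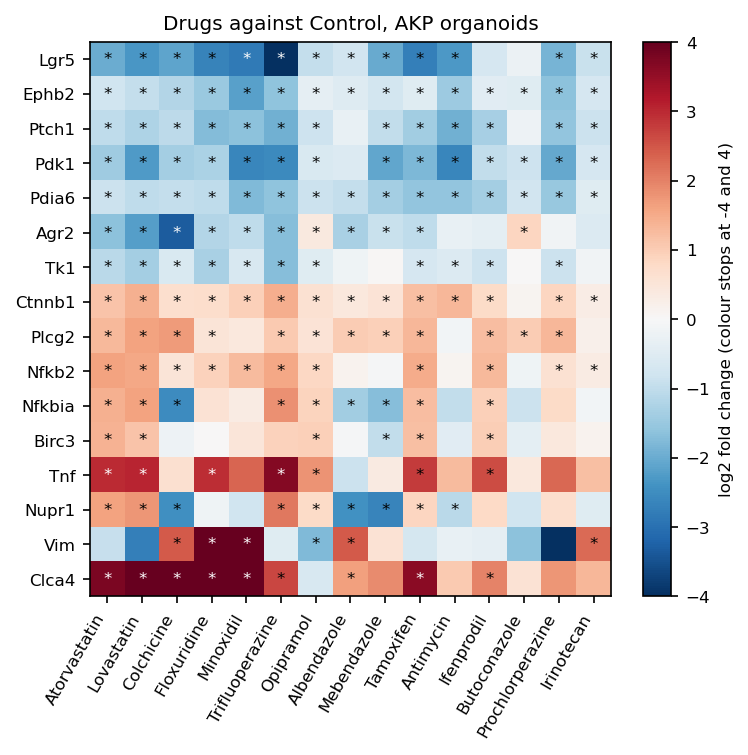
Log2 fold change of 16 genes with each of the 15 drugs in AKP organoids, with the colour scale ending at -4 and 4 and stars where edgeR's adjusted p is under 0.05. Ephb2 and Pdia6 are lower with all 15 drugs and Lgr5 passed in 13.

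The effect of each drug was compared between genotypes by the interaction of drug and genotype. Minoxidil raised Clca4 in AKP (6.13) while the WT value was below 0, a difference of 7.92 ± 0.61, and its effect on Vim was higher in AKP by 5.12 ± 0.90. Its effect on Areg was lower in AKP (-2.45 ± 0.55), as was that of Irinotecan (-1.98 ± 0.52). These effects on Areg were 0.22 and 0.10 in AKP and 2.67 and 2.08 in WT. On the fitted WT plates of these drugs, Areg differed between the median drug well and the Control mean. This difference was 1.36 on Plate 8, 1.05 on Plate 9 and -0.51 on Plate 6 rep. What part of the genotype difference in Areg comes from these Control wells was not tested. Agr2 fell in AKP relative to WT with Colchicine (-2.87 ± 0.43), Atorvastatin (-2.05 ± 0.35) and Lovastatin (-1.98 ± 0.39). With Atorvastatin it was -1.41 in AKP and 0.64 in WT. Muc2 moved down in AKP (-1.54) and up in WT (1.11) with Atorvastatin, a difference of -2.65 ± 0.44. Nupr1 did so with Colchicine (-2.32 and 1.39, difference -3.71 ± 0.48), with which Birc5, a survivin gene expressed in mitosis, differed the other way (4.19 ± 0.57, with 5 counts in the WT drug wells).

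Trifluoperazine lowered Tnfrsf19 in AKP relative to WT (-3.75 ± 0.65) and raised Egfr (1.76 ± 0.39), and Lovastatin raised Clca4 (3.49 ± 0.64). Of 2850 pairs 322 differed, most for Atorvastatin (42), Trifluoperazine (32), Minoxidil (30) and Colchicine (28). Without AKP Atorvastatin replicate 3 the count of Atorvastatin was 28, 20 higher and 8 lower in AKP, and no longer the highest. Ccnd1, Agr2, Ctnnb1 and Clca4 differed in 8 drugs each. The split into 178 higher and 144 lower in AKP turned with the scaling (135 and 190 with DESeq2 size factors, 119 and 234 with total counts), since these moved the median of all genes by up to -0.68 for a single drug, Atorvastatin. The 13 differences named passed under both other scalings, and without AKP Plate 96, which leaves fewer libraries, 175 pairs passed.

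**Figure D5:**
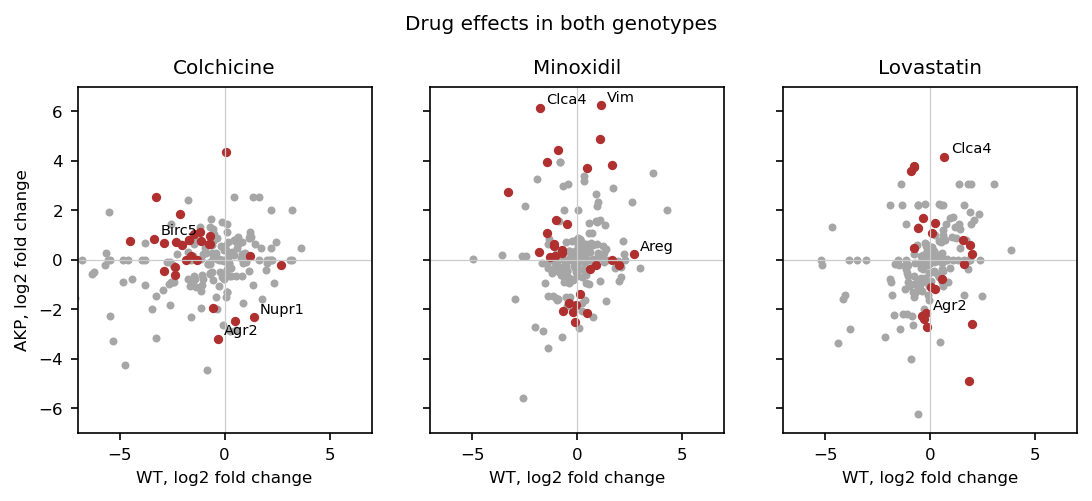
Log2 fold change of each gene in AKP (vertical axis) against WT (horizontal axis) with Colchicine, Minoxidil and Lovastatin, on axes that end at -7 and 7, with red points for genes whose effect differed between genotypes. Nupr1 lies at -2.32 in AKP and 1.39 in WT with Colchicine.

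Structurally related drugs were compared in WT organoids, at doses that the labels do not give, so that matched doses cannot be stated. Colchicine differed from Thiocolchicoside, a glycoside with a sulfur-containing group, in 28 genes: Reg1 by 5.49 ± 0.74 and Anpep by 4.18 ± 0.54 higher, and Birc5 by -3.25 ± 0.57. The enterocyte list differed by 2.72 (95% interval 1.81 to 3.63), the enteroendocrine list by 1.86 (1.15 to 2.58), proliferation by -2.24 (-2.69 to -1.79), the stem cell list by -1.39 (-1.83 to -0.95) and WNT targets by -1.28 (-1.69 to -0.86). Isotretinoin differed from Ret_acid in 24 genes, with Areg higher by 4.13 ± 0.52 and Olfm4 lower (-2.63 ± 0.46), p53 genes by 2.00 (0.88 to 3.11), EGFR genes by 0.82 (0.26 to 1.38) and stem cell genes by -0.52 (-0.83 to -0.21). Trifluoperazine and Prochlorperazine, which share a piperazine side chain and differ at a ring substituent, differed in 5 genes, with Apoa4 (-1.93 ± 0.30) and Sis (-2.58 ± 0.46) lower.

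Of 20 pairs 12 differed in at least 1 gene. In most pairs the drugs share no plate, among them Isotretinoin and Ret_acid and Trifluoperazine and Prochlorperazine. Each drug was then set against other Control wells, so a difference between those wells cannot be told apart from one between the drugs. Colchicine and Thiocolchicoside shared 2 plates. Without 1 of their libraries no gene passed in edgeR for 6 of these, Doxorubicin and Epirubicin (1 gene with all libraries), Doxorubicin and Daunorubicin (3), Albendazole and Parbendazole (1), Mebendazole and Nocodazole (3), Perphenazine and Fluphenazine (2) and Econazole and Isoconazole (2). In edgeR no gene passed for Simvastatin and Lovastatin (9 at unadjusted p under 0.05), Simvastatin and Fluvastatin (6), Terfenadine and its carboxylic acid Fexofenadine (7), Estradiol and Estriol (10), Albendazole and Mebendazole (4), Trifluoperazine and Fluphenazine (16), Floxuridine and fluorouracil (11) or Hydrocortisone and Corticosterone (4). With DESeq2 15 of the 20 pairs differed. Missing the threshold does not show that such drugs act alike. For Terfenadine and Fexofenadine none of 15 list intervals excluded 0 and the widest reached 0.51 to either side of its value, and for Hydrocortisone and Corticosterone it reached 1.00, while for Albendazole and Mebendazole 3 of 14 intervals excluded 0 and for Simvastatin and Lovastatin 4. The count for Colchicine and Thiocolchicoside was 7 without Colchicine replicate 1 on Plate 11, that for Isotretinoin and Ret_acid 14 without Isotretinoin replicate 3 on Plate 8, and that for Trifluoperazine and Prochlorperazine 3 without Prochlorperazine replicate 1 on Plate 71 72. Where a drug had 2 libraries, the 1 left is assumed to vary like the other groups.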

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

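The tests of the Control wells against all drug wells and of permutation plate by plate, those of single Atorvastatin and EECs libraries, and the relabelled splits for the reference conditions, AKP against WT, drugs in AKP, the genotype difference and the analogs were chosen after the results were seen; the other tests were chosen before. Splits of the samples into groups of the same sizes, the real one among them, exclude a chance assignment of the samples as the source of each count, since only 1 split, the real one, gave as many.

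Of 101 splits each, the highest other gave 2 genes for Stem_cells (real 37), 28 for Enterocytes (122), 17 for EECs (104), 28 for IFNg (131), 10 for AKP against WT (135) and 56 pairs for drugs in AKP (726). For the genotype difference the highest of 41 splits other than the real one gave 12 pairs (322), and for the analogs the highest of 51 gave 3 pairs of drugs (12). For the WT screen 21 splits gave at most 9 drugs (70), 276 drug-gene pairs (2400) and 14 drug-list pairs (292), and 101 splits of the drugs into classes, with 10000 resamples, gave at most 7 class-list pairs (24, and 27 with these resamples).

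In plate set B, Ccl6 was lower against Control in 42 of 79 drugs and Defa24 in 39 of 79, and chance error of the Control wells plate by plate is argued against: over 13 plates the mean Defa24 difference between drug and Control wells was -0.84, the largest permuted shift of any gene was 0.78, and 0% of 1000 permutations of Control and drug wells within plates gave a shift as large as the largest real one. Permuted screens gave 1 gene in up to 22 drugs of a set, and on the scaled plate the Defa24 difference was -0.35, and neither decides the point. Control wells that differ from all drug wells may be the source: Defa24 was at -0.80 or below, at the median, even among drugs with under 10 genes in sets A, B and C, and at -0.99 in set D, and against the other drug wells of set B Ccl6 passed for 3 drugs. On Plate 11 of set D the Defa24 difference went the other way, 0.55, with 14.5% of drug wells below the Control mean, as did that of Ccl6 in set B on Plate 6 rep, 1.21 against 1 Control well, and on the scaled plate, 0.18. The vehicle and the well positions are not in the labels, so a response shared by many drugs and a property of the Control wells cannot be told apart here.

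With Atorvastatin in AKP, genes at or near 0 in Control wells were higher (Apoa4, Dll1, Defa17, Adh1 and Reg1). Without replicate 3, 1 of these 5 still passed, Dll1 at 5.44, so a signal of this 1 library may account for the others. It held 133 counts of Apoa4, 83 of Aldob and 1 of Trp53, the only Trp53 count of the 105 AKP libraries. WT transcripts in that library could be the source: a single share of the best matching WT library put 72.7% of 11 genes within a factor of 2, which does not decide it, because the best of 1054 WT libraries was chosen to match. A biological difference of this well was not tested.

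Cxcl9 and Stat1 rose in EECs. A signal of 1 library alone is argued against, since 2 of these 2 genes passed without replicate 1 on Plate 15 (Cxcl9 3.25, Stat1 2.31). For that library, with 7127 counts, IFNg transcripts could add to its Cxcl9: at the 18.6% share that Cxcl9 implies, 88.9% of the 9 other genes raised by IFNg lay within their counting interval, against 4 of 9 at no share. For the other EECs libraries no explanation was tested, and the composition of the EECs condition is not in the labels.

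Single samples stood apart from the others of their group by Dixon's test in 12 of 96 tests, and chance gives about 1 in 20. Values are log2 ratios to the Control wells of the plate, with the nearest sample in parentheses. In Stem_cells replicate 7 on Plate 6 rep was highest for Chgb at 0.31 (-1.33) and for Zg16 at 3.82 (0). In EECs replicate 1 on Plate 16 had the highest total, 48234 counts (13141), and the lowest Axin2, -3.39 (-2.13). Replicate 1 on Plate 1 was lowest for Gip at -4.63 (2.40), Guca2b at -0.80 (1.09) and Bax at -3.24 (-1.45), and replicate 1 on Plate 18 for Scgn at -3.36 (0.99) and Aqp4 at -7.40 (-3.67). In IFNg replicate 1 on Plate 16 was lowest for Ccnd1 at 0.57 (1.15). Among AKP Control plates the plate titled extra was highest for Cd44, 13.74 log2 CPM (13.19), and for Bax, 10.46 (9.22).

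Drug effects differed between the genotypes in 322 drug-gene pairs by the interaction test: Atorvastatin 42, Trifluoperazine 32, Minoxidil 30, Colchicine 28, Irinotecan 23, Lovastatin 22, Antimycin 21, Mebendazole 21, Floxuridine 19, Tamoxifen 19, Opipramol 17, Ifenprodil 15, Albendazole 13, Butoconazole 10 and Prochlorperazine 10. Without AKP replicate 3 Atorvastatin gave 28, with 20 rather than 35 higher in AKP. The effect in AKP minus that in WT was, with Colchicine, -3.71 for Nupr1, -2.87 for Agr2 and 4.19 for Birc5. With Atorvastatin it was -2.65 for Muc2 and -2.05 for Agr2, and with Lovastatin -1.98 for Agr2 and 3.49 for Clca4. With Trifluoperazine it was -3.75 for Tnfrsf19 and 1.76 for Egfr. With Minoxidil it was 5.12 for Vim, 7.92 for Clca4 and -2.45 for Areg, and with Irinotecan -1.98 for Areg. Both Areg values rest on WT plates where Areg also differed between Control wells and drug wells at large, as given above.

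AKP wells with a single library per drug were in no test. The number of the 149 genes that lay beyond every one of the 29 Control libraries was 92 with Daunorubicin, 74 with Clomiphene, 74 with Thiethylperazine, 64 with Perphenazine, 58 with Doxorubicin, 55 with Pyrvinium, 51 with Azaguanine, 48 with Gemcitabine and 47 with Nocodazole, against at most 44 (median 3) for a Control library set against the others. Daunorubicin held 2295 counts, Pyrvinium 3359 and Thiethylperazine 4934, below the 10533 of the shallowest AKP Control library, so the Control range gives no measure of what low depth alone does there. After 1 day it was 59 with Butoconazole and 59 with Lovastatin, against at most 55 (median 34.5) among 8 Control libraries.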

How the results depend on the processing

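The alternatives with the scaled plate, without the Defa6 values, and leaving out single EECs, Stem_cells, IFNg or AKP drug libraries or, for the genotype difference, AKP plates were chosen after the data were seen. Every count not named below stayed within 1.5 times its value under each alternative run: Enterocytes 82 to 137 (122), EECs 72 to 127 (104), IFNg 104 to 137 (131), AKP against WT 120 to 141 (135), Stem_cells 32 to 49 (37), class-list pairs 20 to 27 (24), drug-list pairs 229 to 384 (292), drugs of the screen 66 to 83 (70), their pairs 2185 to 2753 (2400), pairs in AKP 576 to 747 (726), genotype differences 288 to 385 (322) and analog pairs 12 to 15 (12), with the exceptions that follow. Without a plate term Stem_cells gave 22 genes (37 with it), and the screen 19 drugs and 604 pairs (70 and 2400). A replicate block, the replicate number in place of plate, gave 24 genes for Stem_cells, 75 for Enterocytes, 250 drugs and 6384 pairs for the screen, 139 pairs for the genotype difference (322) and 3 analog pairs (12), and changed no other count by as much. Other drug wells in place of Control gave 24 drugs and 827 pairs. The cause was not tested for any of these.

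Leaving out libraries or plates gave 31 to 39 genes for Stem_cells, 96 to 106 for EECs and 125 to 134 for IFNg, 48 to 73 drugs and 1916 to 2533 pairs for the screen, 382 to 749 pairs for drugs in AKP (726) and 11 to 13 analog pairs. Without Plate 95 the AKP drugs gave 388 pairs and without Plate 96 382, since 1184 and 1144 of the 2235 pairs could then be tested. The genotype difference gave 175 to 324 pairs, with 210 without AKP Plate 95, 175 without Plate 96 and 214 without Plate 99, since fewer libraries are left.

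Of the 193 named values, all 193 kept direction and side of the threshold with DESeq2 size factors and 192 with total counts, where Lgr5 in AKP against WT was 0.26 (-0.09 with TMM), not past either way. Without a plate term 134 stayed, 13 kept their direction and lost the call, and Lgr5 in Stem_cells was 0.67 (-0.15); the cause was not tested. The 13 include Fabp1 (1.06), Muc2 (-0.84) and Zg16 (-0.71) in Stem_cells and Clca4 with Pyrvinium (-2.18). Some lost the call at a like size, such as Cd44 in Stem_cells (0.61, and 0.57 with the plate term) and Ay761184 with Azaguanine (1.83 and 1.79). Values without a plate term were not run for AKP against WT, the genotype difference and the analogs. Of 2-fold changes the simulated data recovered 20% for AKP against WT and 9% for the genotype difference, and whether depth is the cause was not tested.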

Other observations

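The statin and phenothiazine test and the genotype likeness test below were chosen before their results were seen. Further genes passed with many of the drugs in AKP, which share the Control wells of their plates. Cdx2, the intestinal homeobox factor, fell with 12 of the 15 drugs, Scd2, a fatty acid desaturase, with 12, Rbpj, the transcription factor of Notch signalling, with 12, and Cdkn1b, a cell cycle inhibitor, with 10, while Rela, an NF-kB subunit, and Clca4 rose with 9 each. Muc2 fell with 8, as did Vegfa, a vascular growth factor. Tnf rose with 7. These genes were chosen after their values were seen.

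Among WT drugs a hypothesis was that statins and phenothiazines change the same genes in the same direction. The mean correlation across 170 genes between 2 statins and 4 phenothiazines of plate sets A to D, each gene centred on the median drug of its set, was 0.31, above 99.3% of 10000 draws of drugs matched by the number of genes changed, whose median was 0.10. Genes are not independent replicates here. In 20 permuted screens the mean correlation was at most 0.05. Centring on the median drug takes out an error of the Control wells that all drugs of a set share. A low value was thus likely in advance, and whether shared wells contribute to the correlation is not decided. The single pairs differed: those with Perphenazine and Thiethylperazine lay between 0.43 and 0.63, while Atorvastatin had 0.09 with Trifluoperazine and 0.09 with Piperacetazine, and Lovastatin 0.21 and 0.15. A likeness of statins to Perphenazine and Thiethylperazine thus stays a hypothesis, one of the classes as a whole is not shown, and which genes carry it was not tested.

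Another hypothesis was that a drug gives like changes in WT and AKP organoids, because its targets are the same. It was not borne out as a whole. Over 15 drugs the mean correlation across 108 genes was 0.10, and 38.0% of random pairings of drugs between the genotypes gave less. The own WT profile ranked first for 1 drug, and the highest correlations were those of Atorvastatin (0.52) and Lovastatin (0.45). In AKP both of these drugs sat on 1 plate and shared its Control wells.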
